A study of Mus musculus with 10 samples.

How the data were processed

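Bone marrow mesenchymal stromal cells from 5 independent preparations were profiled on 10 single-colour arrays, 2 per preparation, from biotin-labelled total RNA. The grouping was taken from the sample titles. The deposited table held log2 expression values of 35399 probe sets, with no missing value and no pair of arrays with identical values. Per the submitters' processing notes, RMA and Partek were used, in versions not given in the sources used here. RMA corrects the background, normalises arrays to a common distribution by quantiles and summarises the probes of a set on the log2 scale. It compresses differences between low values, and no detection calls were used, so a low level is not evidence that a transcript was absent. Read alignment, peak calling and genome builds of the authors do not apply to these arrays. No column of per-sample values was left unused.

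Probe sets were named from the platform annotation of the array. In it 21789 probe sets had 1 gene symbol, 1621 had several and 11989 had none, and only those with 1 symbol were used. Of these, 21698 matched a gene of the mouse reference (assembly GRCm38.p6) through their gene identifier, which was used for current symbols, chromosomes and the order of genes along them. Probe sets with no listed symbol are unnamed here and may still measure a known gene: 2272 of 21900 protein-coding genes of the reference had no entry in the annotation. The named probe sets covered 19938 genes, 999 of them with more than 1 probe set, of which the one with the highest mean was used. Genes were tested where at least 2 arrays lay above the median of the table (6.55 log2), which left 10972.

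Preparation means were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with tables and figures prepared in Python 3.11.15. Differences over all preparations were tested with the moderated F statistic, and each preparation against the other four, as well as each pair, with limma's moderated statistic. All 10 arrays shared 1 estimate of the replicate spread. The p-values were two-sided and adjusted by Benjamini-Hochberg over genes. A gene was called at an adjusted p under 0.05 and a difference of at least 1 log2, a fold of 2. Errors after a difference are standard errors from the fit, and errors after a level are SD over 2 arrays. The SE in the tests of X genes are over genes instead. Differences between preparations are given as this preparation minus the mean of the other four.

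A set of 32 gene lists with 598 entries covered stromal, bone, fat and cartilage genes, signalling and metabolic pathways, imprinted and Hox genes, and markers of other cell types. Of the entries, 546 had a probe set with that symbol alone, 14 appeared on probe sets with several symbols only, and 38 had no symbol in the annotation used and were not analysed here, Runx2, Spp1, Bglap and Trp53 among them. The entry Rigi was matched to Ddx58 through a synonym in the reference only after the results had been seen, which changed no call. The 26 lists with at least 4 tested members were tested with limma's camera at the preset correlation of 0.01, adjusted over all lists and preparations. The genes of the 20 chromosomes (287 to 899 tested genes each) were tested in the same way.

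The lists, the main tests, the thresholds for calls and the rule for named genes were fixed before the data were examined. Tests of male cells, of renewed X expression, of blood cells and of a shift of all genes were chosen after the results were seen. So were the minimum for the chromosome shifts and the demand that a value pass its bound by more than its spread. The rule took, for each preparation, the 14 genes with the largest positive and the 10 with the largest negative difference among called genes whose 2 arrays both lay outside the range of all other arrays, without predicted or clone names. It also took the 10 genes with the widest range of preparation means, and allowed every list member to be named with its value. Not every gene that the rule took is named in the text, and genes whose call depended on 1 array were named less often, a choice made after seeing the data.

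The alternatives were no low-value filter, a stricter filter at the 75th percentile of the table (9.22 log2) and the mean of a gene's probe sets. Others were arrays centred on their medians, a further quantile normalisation, eBayes with trend and robust settings, the replicate number as a block, each array left out in turn, the arrays of a pair alone, and each preparation as 1 value set against the spread of the other four. Where leaving out an array left a preparation with 1 array, that array was assumed to vary like the others, and genes that passed the filter in that preparation alone were not tested. Lists and chromosomes were also tested with an estimated correlation and with fry. Leaving MSC I out of the reference of the other preparations was added after seeing the data.

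The scripts were tested on simulated data for MSC I against the other four, with 10972 genes of which 200 were changed. The fit recovered 88% of the genes changed by 1.5 log2 and 99% of those changed by 3 log2, and called 4 unchanged genes. Camera called a simulated shifted list and a simulated shifted chromosome-sized set, and called 0 of 100 unshifted random lists. The simulated genes varied independently of each other. The simulation therefore does not show how often camera calls unshifted lists whose genes are correlated.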

Results

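Gene expression was measured in bone marrow mesenchymal stromal cells, the adherent fibroblast-like cells of the marrow that can form bone and fat and that supply blood stem cells with growth factors. The cells came from female mice of the inbred C57BL/6J strain aged 6 to 8 weeks and were studied at passage 16 to 17. There were 5 independent preparations, named MSC I to MSC V, with 2 arrays each and 10 arrays in all. Total RNA was hybridised to a whole-transcript oligonucleotide array with 35399 probe sets, and the deposited values were log2 expression levels. The median level of an array lay between 6.45 (MSC V, replicate 1) and 6.63 (MSC IV, replicate 1). No preparation was named as a control, so each was set against the unweighted mean of the other four, and all pairs were compared as well. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these arrays, which may be technical, and the number of arrays limits the precision.

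MSC I and MSC IV stood apart from each other and from MSC II, III and V. On the first principal component the arrays of MSC I and MSC IV lay at opposite ends, and on the second component both lay on one side and the other preparations on the other. The arrays of one preparation correlated at r = 0.971 to 0.982 across 10972 genes, while arrays of different preparations correlated at r = 0.760 (MSC I with MSC IV) to 0.955 (MSC III with MSC V). The mean distance, taken as 1 minus r, was 0.0241 within preparations and 0.118 between them, and each of the 10 arrays was nearest to its own replicate. An exact one-sided permutation test over the 945 ways to pair the arrays gave p = 0.00106, and over the 120 ways that join a replicate 1 to a replicate 2 it gave p = 0.00833, in both cases the smallest value the test can give. Genes are not independent replicates, so the correlations describe the arrays and carry no p of their own.

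**Figure D1:**
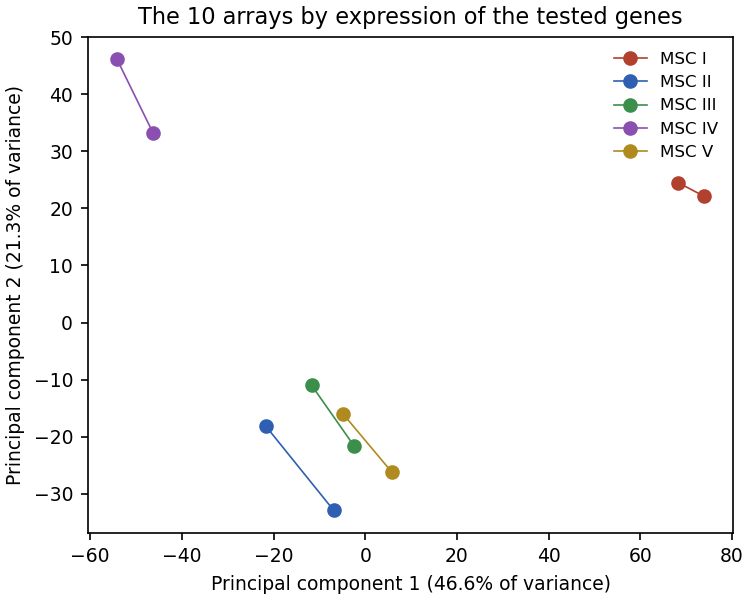
Scores of the 10 arrays on the first principal component (horizontal axis, 46.6% of variance) and the second (vertical axis, 21.3% of variance) of the log2 levels of the tested genes; each colour is a preparation and a line joins its 2 arrays. MSC I and MSC IV lie apart from each other and from the remaining preparations.

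The question of how far independent preparations of one cell type differ was asked first over all of them. Kcnma1, a calcium-activated potassium channel, had a range of 8.44 log2 between MSC II and MSC V (adjusted p = 4.5e-05). Its mean ± SD (n = 2) was 13.83 ± 0.41 in MSC III, close to MSC II, and 5.56 ± 0.0625 in MSC V. Ibsp, the bone matrix protein bone sialoprotein, ranged from 5.12 ± 1.63 in MSC I to 13.54 ± 1.28 in MSC IV (range 8.43, adjusted p = 0.00729). The citrate transporter Slc13a5 (range 7.67, adjusted p = 8.95e-05) and the channel protein Panx3 (6.90, adjusted p = 1.02e-05) were highest in MSC IV. The retinoic acid synthesising enzyme Aldh1a2 (7.63, adjusted p = 0.000269) and the matrix glycoprotein Efemp1 (7.28, adjusted p = 0.000184) were highest in MSC I. So were the fatty acid receptor Cd36 (7.24, adjusted p = 5.98e-07), the interferon-induced protease Usp18 (7.16, adjusted p = 1.4e-06) and the complement inhibitor Serping1 (6.81, adjusted p = 2.59e-05). The membrane protein Itm2a (7.11, adjusted p = 6.09e-05) was highest in MSC II. The lowest means of these genes lay under the low-value level of 6.55, so the ranges are lower bounds and their order is not fixed. In limma's moderated F test with Benjamini-Hochberg adjustment, 3192 of 10972 genes (29.1%) differed among the preparations by at least 1 log2. MSC I held the highest mean for 1212 of them and MSC IV the lowest mean for 1169. The preparation accounted for 87.6% of the variance of the tested genes, with a median replicate SD of 0.180 log2 and a median SD of 0.303 log2 among preparation means. All 21 tested interferon response genes differed, as did 25 of 27 Hox genes, which encode the positional transcription factors of the body axis, and 12 of 13 imprinted genes. None of 10 housekeeping genes did. Without replicate 1 or replicate 2 of MSC I, 13 interferon response genes passed the low-value filter, and all 13 differed.

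MSC I was set apart by genes of the interferon response and of fat cells. Of the 21 tested interferon response genes, 20 were higher than in the other four (median 3.53, adjusted p = 7.46e-19, and adjusted p = 0.0754 with an estimated correlation). The count was 20 when adjusted over the list alone. They included Usp18 (6.64 ± 0.13 log2, SE), the transcription factor Irf7 (5.44 ± 0.11), the antiviral proteins Ifit3 (4.99 ± 0.22) and Oasl2 (5.10 ± 0.17) and the RNA sensor Ddx58 (2.56 ± 0.12). Irf1 was the member that was not called (0.93 ± 0.16, adjusted p = 0.00307). Of 10 genes of class I antigen presentation, 7 were higher (median 1.38, adjusted p = 3e-07, and adjusted p = 0.334 with an estimated correlation). The count was 7 when adjusted over the list alone. The higher genes included the peptide transporter Tap1 (3.21 ± 0.16) and the class I gene H2-Q4 (5.45 ± 0.20). Of 12 adipocyte genes, 10 were higher (median 3.55, adjusted p = 3e-07, and adjusted p = 0.397 with an estimated correlation). The count was 10 when adjusted over the list alone. Cd36 had the largest difference of the genes named (7.15 ± 0.0961, adjusted p = 3.47e-08), with a mean ± SD of 12.18 ± 0.15 in MSC I (n = 2). Other higher members were adiponectin, Adipoq (5.44 ± 0.25), lipoprotein lipase, Lpl (4.69 ± 0.69), and the fatty acid carrier Fabp4 (4.09 ± 0.38). Some of these genes passed the low-value filter in MSC I alone and could then only be higher there. The filter itself therefore added to the list medians and calls above. Without one of the MSC I arrays these genes were not tested. Interferon response calls were then 12 of 13 tested genes without MSC I replicate 1 and 13 of 13 without replicate 2. Adipocyte calls were 6 of 8 without either replicate, and class I calls 4 of 8 without replicate 1.

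Further genes were higher in MSC I. They were the iron carrier transferrin, Trf (6.61 ± 0.23, adjusted p = 1.28e-06), Aldh1a2 (6.47 ± 0.45), the Tie2 ligand Angpt2 (6.21 ± 0.14), Serping1 (5.87 ± 0.25), the chemoattractant chemerin, Rarres2 (5.77 ± 0.26), and the chemokine Cxcl14 (5.15 ± 0.16). Of 14 haematopoietic niche factors, which support blood stem cells, 9 were higher and 2 lower (median 1.49, adjusted p = 0.0166, and adjusted p = 0.772 with an estimated correlation). The counts were 9 and 3 when adjusted over the list alone. The 2 lower genes fell to 0 without MSC I replicate 2, and to 1 without MSC I replicate 1, MSC II replicate 2, MSC III replicate 2, MSC IV replicate 1 or MSC V replicate 1. Of 10 inflammatory cytokines and chemokines 5 were higher, the cytokine Il6 (3.31) and the chemokines Ccl2 (4.23), Ccl7 (3.21), Ccl5 (2.44) and Cxcl1 (1.08), and the list was called (median 1.35, adjusted p = 0.011, and adjusted p = 0.772 with an estimated correlation). Cxcl1 was under the minimum without MSC V replicate 2, at 0.99. The count was also 5 when adjusted over the list alone. That call was lost without the low-value filter (adjusted p = 0.125) and with the stricter one (adjusted p = 0.101). Of 27 proliferation genes 6 were higher (median 0.99, adjusted p = 0.000763, and adjusted p = 0.831 with an estimated correlation). The count was 5 when adjusted over the list alone. It depended on single arrays, with 1 gene called without MSC I replicate 1, 0 without MSC I replicate 2, and 12 without MSC II replicate 2 or MSC V replicate 1. Of 13 imprinted genes 4 were higher and 1 lower (median 0.55, adjusted p = 0.0408, and adjusted p = 0.72 with an estimated correlation). The counts were 5 and 1 when adjusted over the list alone. The imprinted call was lost without MSC I replicate 1 (adjusted p = 0.103), without MSC II replicate 1 (adjusted p = 0.077) and without the low-value filter (adjusted p = 0.0909). The lowest genes in MSC I were the matrix protein periostin, Postn (-5.74 ± 0.29, adjusted p = 7.11e-06), the cytoskeletal regulator Dpysl3 (-5.61 ± 0.20), Ibsp (-5.58 ± 0.92), Itm2a (-5.42 ± 0.32), the cadherins Cdh3 (-4.91 ± 0.17) and Cdh2 (-4.71 ± 0.19), and the osteoblast transcription factor Dlx5 (-4.38 ± 0.41). Of 12 osteoblast genes 5 were lower and 1 higher, also when adjusted over the list alone, and the list was not called (median -1.36, adjusted p = 0.053, and adjusted p = 0.752 with an estimated correlation). In all, limma called 848 genes higher and 573 lower in MSC I.

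**Figure D2:**
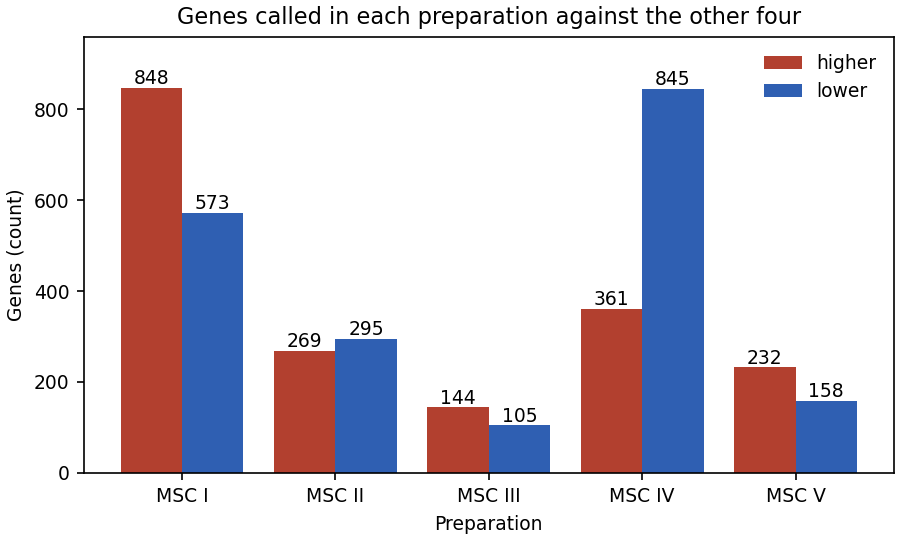
Number of genes (vertical axis) called higher (red) and lower (blue) in each preparation (horizontal axis) against the mean of the other four, at an adjusted p under 0.05 and a difference of at least 1 log2. MSC I has the most higher genes, 848, and MSC IV the most lower genes, 845.

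MSC II was marked by its Hox genes. Of 27 tested, 12 were higher and 3 lower (median 0.88, adjusted p = 0.00995, and adjusted p = 0.72 with an estimated correlation). The counts were 12 and 3 when adjusted over the list alone. Without MSC II replicate 2 the higher genes were 4 of 24 tested. All 7 tested genes of the Hoxb cluster were higher, from Hoxb9 (3.50 ± 0.20) and Hoxb2 (2.55 ± 0.18) to Hoxb7 (1.26 ± 0.15). Without MSC II replicate 2 some Hoxb genes fell under the low-value filter and were not tested. The calls of Hoxa9, Hoxc5, Hoxc6, Hoxc8 and Hoxc9 were lost without that array. The list's call was lost without MSC II replicate 1 (adjusted p = 0.0655), without MSC II replicate 2 (adjusted p = 0.206) and with the stricter low-value filter (adjusted p = 0.0518). Higher genes outside the list were the ribosomal protein gene Rpl39l (5.32 ± 0.11, adjusted p = 8.35e-07), the calcium-binding protein Efhd1 (4.34 ± 0.10), Plac8 (4.11 ± 0.13), the guanylate-binding protein Gbp9 (4.02 ± 0.15) and the neuregulin receptor Erbb4 (3.55 ± 0.42). So were Itm2a (3.47 ± 0.32), the retinoic acid carrier Crabp1 (3.44 ± 0.39) and the actin regulator Wasf3 (3.48 ± 0.25). Lower genes were the membrane proteins Tmem176a (-3.97 ± 0.29, adjusted p = 0.000307) and Tmem176b (-3.46 ± 0.25), the glycoprotein Gpnmb (-3.57 ± 0.43), the protease Ctsc (-2.77 ± 0.26) and the osteoclast inhibitor osteoprotegerin, Tnfrsf11b (-2.73 ± 0.23).

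The proliferation list was lower in MSC II (median -0.75, adjusted p = 0.000763, and adjusted p = 0.831 with an estimated correlation), with 1 of 27 genes called over all genes and 0 when adjusted over the list alone. That gene, the replication enzyme Rrm2 (-2.06 ± 0.45, adjusted p = 0.0186), lost its call without MSC II replicate 1 (adjusted p = 0.126) or replicate 2 (adjusted p = 0.0764). The list had 0 genes called without MSC II replicate 1 and 2 without MSC V replicate 2. Its median was -0.31 (adjusted p = 0.149) without MSC II replicate 1 and -1.24 (adjusted p = 1.06e-06) without MSC II replicate 2. The median was -0.48 with MSC I left out of the reference (adjusted p = 0.0113, and adjusted p = 0.899 with an estimated correlation). The adipocyte list (median -0.82, adjusted p = 0.000555, and adjusted p = 0.67 with an estimated correlation), the interferon response list (median -0.92, adjusted p = 2.22e-08, and adjusted p = 0.126 with an estimated correlation) and the class I list (median -0.28, adjusted p = 0.0138, and adjusted p = 0.72 with an estimated correlation) were lower. They had 3 of 12, 10 of 21 and 1 of 10 genes called, the same numbers when adjusted over each list alone. The counts were 1, 6 and 0 without replicate 1 or replicate 2 of MSC I, with 8, 13 and 8 genes tested, and the interferon count was 6 without MSC II replicate 2. These 3 calls ended with MSC I left out of the reference, where their medians were -0.00022 (adjusted p = 0.859), -0.0524 (adjusted p = 0.934) and 0.11 (adjusted p = 0.765). The adipocyte call was also lost without MSC I replicate 1 (adjusted p = 0.0986), and the class I call without MSC I replicate 1 (adjusted p = 0.143) or MSC II replicate 1 (adjusted p = 0.077). In all, 269 genes were called higher and 295 lower in MSC II, 564 together, and 295 together without MSC II replicate 2.

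**Figure D3:**
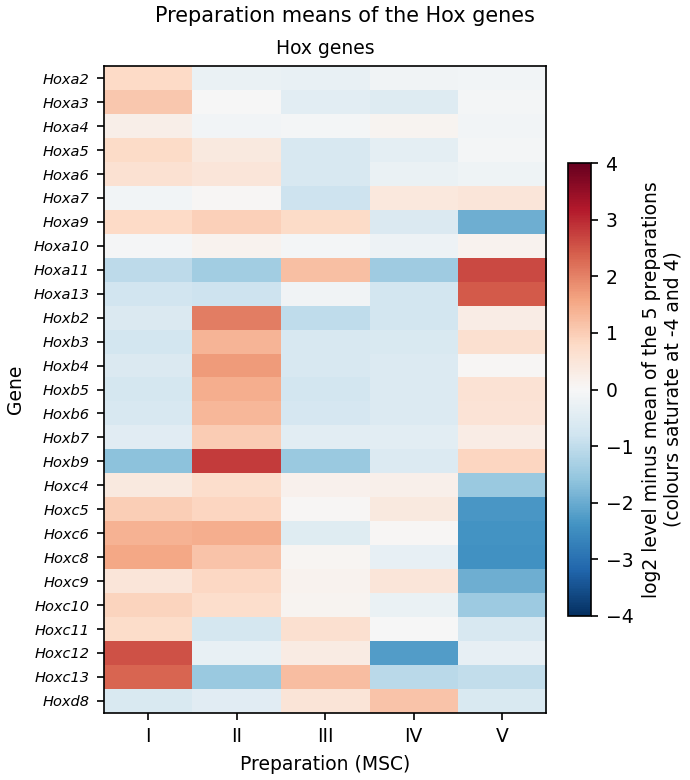
Mean log2 level of each tested Hox gene (vertical axis) in each preparation (horizontal axis), as the colour-coded difference from the mean of the 5 preparations, saturating at 4 log2 in either direction. Red is higher and blue is lower, with the Hoxb block red in MSC II and the Hoxc block blue in MSC V.

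MSC III had the fewest called genes of the 5 preparations. Its higher genes were Nlrp2 (3.91 ± 0.27, adjusted p = 0.000434), a member of the innate sensor family, the pterin-recycling enzyme Pcbd1 (3.54 ± 0.35), the growth factor binding protein Igfbp6 (3.47 ± 0.19) and the matrix protein tenascin N, Tnn (3.38 ± 0.22). The transcription factor Tfap2a (2.85 ± 0.0787), the GABA receptor subunit Gabrb1 (2.38 ± 0.30) and the ubiquitin ligase Hecw1 (2.36 ± 0.19) were higher as well. Its lower genes were Asb4 (-4.38 ± 0.20, adjusted p = 0.000121), the lipase family gene Lipo3 (-3.89 ± 0.16), the mitochondrial carrier Slc25a23 (-2.03 ± 0.15) and Creld1 (-2.03 ± 0.20). Of 25 structural matrix genes 3 were higher, the matrix proteins Fbln2, Postn and Vcan (median 0.27, adjusted p = 0.00304, and adjusted p = 0.788 with an estimated correlation). The count was 4 when adjusted over the list alone, 1 without MSC III replicate 1 and 0 without MSC III replicate 2. The list's median was 0.14 without MSC II replicate 1, 0.16 without MSC III replicate 2 and 0.53 with MSC I left out of the reference (adjusted p = 0.00137, and adjusted p = 0.803 with an estimated correlation). In MSC IV, which was part of the reference and was not left out, this list was lower (median -1.06). The higher list of MSC III was not separated from that. Fbln2 lost its call without MSC III replicate 2 (adjusted p = 0.101). Postn lost it without MSC III replicate 1 (adjusted p = 0.12) or 2 (adjusted p = 0.114) and with MSC I left out of the reference (adjusted p = 0.325). Vcan lost it without MSC III replicate 1 (adjusted p = 0.0954) or 2 (adjusted p = 0.223) or MSC I replicate 1 (adjusted p = 0.0533). The glycolysis and hypoxia list was higher (median 0.30, adjusted p = 0.00259, and adjusted p = 0.752 with an estimated correlation). It had 1 of 20 genes called, also 1 when adjusted over the list alone. Without MSC III replicate 2 the list's adjusted p was 0.16. The gene was the glucose transporter Slc2a3 (1.05 ± 0.11, adjusted p = 0.00281), whose difference was 0.90 without MSC III replicate 1 and 0.69 with MSC I left out of the reference, both under the minimum of 1.

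The proliferation list was higher in MSC III (median 0.51, adjusted p = 0.00259, and adjusted p = 0.831 with an estimated correlation) although limma called 0 of its 27 genes, and 0 when adjusted over the list alone. Its median was 0.92 (adjusted p = 4.57e-07) without MSC III replicate 1 and 0.11 (adjusted p = 0.528) without MSC III replicate 2. The median was 0.78 with MSC I left out of the reference (adjusted p = 1.24e-05, and adjusted p = 0.803 with an estimated correlation). In MSC IV, which was part of the reference and was not left out, the proliferation list was lower (median -1.41). The higher list of MSC III was not separated from that. The adipocyte (median -0.46, adjusted p = 0.00995, and adjusted p = 0.752 with an estimated correlation), interferon response (median -0.55, adjusted p = 1.47e-11, and adjusted p = 0.0811 with an estimated correlation) and class I lists (median -0.34, adjusted p = 0.00426, and adjusted p = 0.67 with an estimated correlation) were lower. They had 3 of 12, 3 of 21 and 1 of 10 genes called, the same numbers when adjusted over each list alone. The counts were 0, 1 and 0 without replicate 1 or replicate 2 of MSC I, with 8, 13 and 8 genes tested, and 1, 1 and 0 without MSC III replicate 2. The adipocyte count was 1 without MSC III replicate 1, and the class I count 0 without replicate 2 of MSC II, MSC IV or MSC V. With MSC I left out of the reference all 3 medians turned positive, at 0.14 (adjusted p = 0.204), 0.0936 (adjusted p = 0.0442, and adjusted p = 0.752 with an estimated correlation) and 0.0453 (adjusted p = 0.389). The adipocyte call was also lost without MSC I replicate 1 (adjusted p = 0.673) or replicate 2 (adjusted p = 0.426), and the class I median was -0.22 without MSC III replicate 2. In all, 144 genes were called higher and 105 lower in MSC III, 249 together, with 82 without MSC III replicate 1 and 76 without MSC III replicate 2.

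MSC IV had higher levels of several genes of osteoblasts, without a call of the osteoblast list, and lower levels of many matrix, niche and contractile genes. Panx3, a channel of bone and cartilage cells, was higher by 6.65 ± 0.22, adjusted p = 7.27e-06, with a mean ± SD of 11.85 ± 0.39 (n = 2). The osteoblast transcription factor osterix, Sp7 (4.57 ± 0.57), the parathyroid hormone receptor Pth1r (4.12 ± 0.38), the osteoblast membrane protein Ifitm5 (4.57 ± 0.43) and osteocrin, Ostn (5.77 ± 0.67), were higher. So were Slc13a5 (6.34 ± 0.36), the Wnt inhibitor Dkk1 (5.22 ± 0.51) and the receptor phosphatase Ptprz1 (4.97 ± 0.47). Ibsp (4.95 ± 0.92, adjusted p = 0.00643) and the mineralisation enzyme alkaline phosphatase, Alpl (3.76 ± 0.75, adjusted p = 0.00856), lost their calls without MSC IV replicate 1, with differences of 4.05 (adjusted p = 0.0597) and 2.97 (adjusted p = 0.0772). Of 12 osteoblast genes 5 were higher and 1 lower, with 6 and 1 when adjusted over the list alone, and the list itself was not called (median 1.26, adjusted p = 0.0835, and adjusted p = 0.772 with an estimated correlation). The lower gene lost its call without MSC IV replicate 2, leaving 0. Runx2, Spp1 and Bglap, central genes of bone formation, were not analysed here because no probe set carried their names.

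Of 14 haematopoietic niche factors 9 were lower in MSC IV (median -2.12, adjusted p = 0.000509, and adjusted p = 0.67 with an estimated correlation). There were 11 lower and 1 higher when adjusted over the list alone. Over all genes 5 were lower without MSC IV replicate 2, and 1 was higher without MSC III replicate 2 or MSC V replicate 1, against 0 with all arrays. The lower genes included the chemokine Cxcl12, which retains blood stem cells in the marrow (-3.13 ± 0.24), stem cell factor, Kitl (-3.12 ± 0.50), and the adhesion molecule Vcam1 (-3.49 ± 0.25), of which Kitl lost its call without MSC IV replicate 2 (-2.51, adjusted p = 0.0521). Of 25 structural matrix genes 12 were lower and 1 higher, also when adjusted over the list alone (median -1.06, adjusted p = 0.00152, and adjusted p = 0.773 with an estimated correlation), with the proteoglycan Vcan at -4.79 ± 0.20 and thrombospondin 2, Thbs2, at -2.72 ± 0.13. The list's median was -1.61 without MSC IV replicate 1 and -0.45 without MSC IV replicate 2. Periostin, Postn, was the higher gene (1.10 ± 0.29, adjusted p = 0.0248), and its difference turned to -0.36 (adjusted p = 0.411) with MSC I left out of the reference. Its call was also lost without MSC I replicate 2 (0.985), MSC II replicate 1 (0.999), MSC IV replicate 1 (0.92) or MSC IV replicate 2 (1.28, adjusted p = 0.0965). The basement membrane protein Nid1 (-5.48 ± 0.19, adjusted p = 9.86e-06), Glipr1 (-5.06 ± 0.16), the Wnt antagonist Sfrp1 (-4.60 ± 0.31) and the matrix-associated protein Ccn3 (-4.25 ± 0.42) were also among the lowest. Of 12 contractile genes 7 were lower, also when adjusted over the list alone (median -1.13, adjusted p = 3.03e-06, and adjusted p = 0.474 with an estimated correlation), with transgelin, Tagln (-2.52 ± 0.13), and enteric smooth muscle actin, Actg2 (-3.88 ± 0.16), among them.

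Of 27 proliferation genes 13 were lower in MSC IV (median -1.41, adjusted p = 2.04e-06, and adjusted p = 0.773 with an estimated correlation). The count was 21 when adjusted over the list alone. The replication helicase subunit Mcm6 was among the lower genes (-1.83 ± 0.23). Without MSC IV replicate 2 the count over all genes was 2 and the list's median -0.94. The count was 8 with MSC I left out of the reference. Of 21 interferon response genes 15 were lower (median -1.58, adjusted p = 4.63e-13, and adjusted p = 0.0811 with an estimated correlation). Of 10 class I genes 5 were lower (median -1.04, adjusted p = 1.59e-05, and adjusted p = 0.397 with an estimated correlation). Of 10 inflammatory cytokines and chemokines 4 were lower (median -1.10, adjusted p = 0.00562, and adjusted p = 0.752 with an estimated correlation). These counts were 15, 5 and 5 when adjusted over each list alone. With MSC I left out of the reference the interferon median was -0.69 with 8 lower (adjusted p = 1.24e-05, and adjusted p = 0.752 with an estimated correlation). The class I median was then -0.60 with 2 lower (adjusted p = 0.00241, and adjusted p = 0.752 with an estimated correlation). The inflammatory median was -0.69 with 4 lower (adjusted p = 0.0183, and adjusted p = 0.803 with an estimated correlation). Of 20 growth factors 8 were lower and 2 higher, also when adjusted over the list alone (median -0.92, adjusted p = 0.0465, and adjusted p = 0.533 with an estimated correlation). There were 4 lower without MSC IV replicate 2. The list's call was lost without MSC I replicate 2 (adjusted p = 0.0776), MSC II replicate 1 (adjusted p = 0.077) or MSC IV replicate 2 (adjusted p = 0.0653). It was also lost with the arrays centred (adjusted p = 0.0582), normalised once more (adjusted p = 0.0601), filtered more strictly (adjusted p = 0.141) or MSC I left out of the reference (adjusted p = 0.149). Of 27 Hox genes 3 were lower and 1 higher, also when adjusted over the list alone (median -0.50, adjusted p = 0.0289, and adjusted p = 0.752 with an estimated correlation). The Hox call was lost without MSC II replicate 1 (adjusted p = 0.0881), MSC II replicate 2 (adjusted p = 0.115), MSC V replicate 1 (adjusted p = 0.0598) or MSC V replicate 2 (adjusted p = 0.0503). The same call was lost without the low-value filter (adjusted p = 0.146), with the stricter one (adjusted p = 0.147) and with MSC I left out of the reference (adjusted p = 0.136). Without MSC IV replicate 2 the Hox median was -0.24. Without replicate 1 or replicate 2 of MSC IV 0 of 26 tested Hox genes were higher, and 6 were lower with MSC I left out of the reference. The adipocyte list was lower (median -1.20, adjusted p = 0.00168, and adjusted p = 0.692 with an estimated correlation). It had 5 of 12 genes called, also 5 when adjusted over the list alone, and 3 of 8 tested without MSC I replicate 1. Its median was -0.0224 (adjusted p = 0.688) with MSC I left out of the reference. In all, 361 genes were called higher and 845 lower in MSC IV, 1206 together, and 703 together without MSC IV replicate 2.

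**Figure D4:**
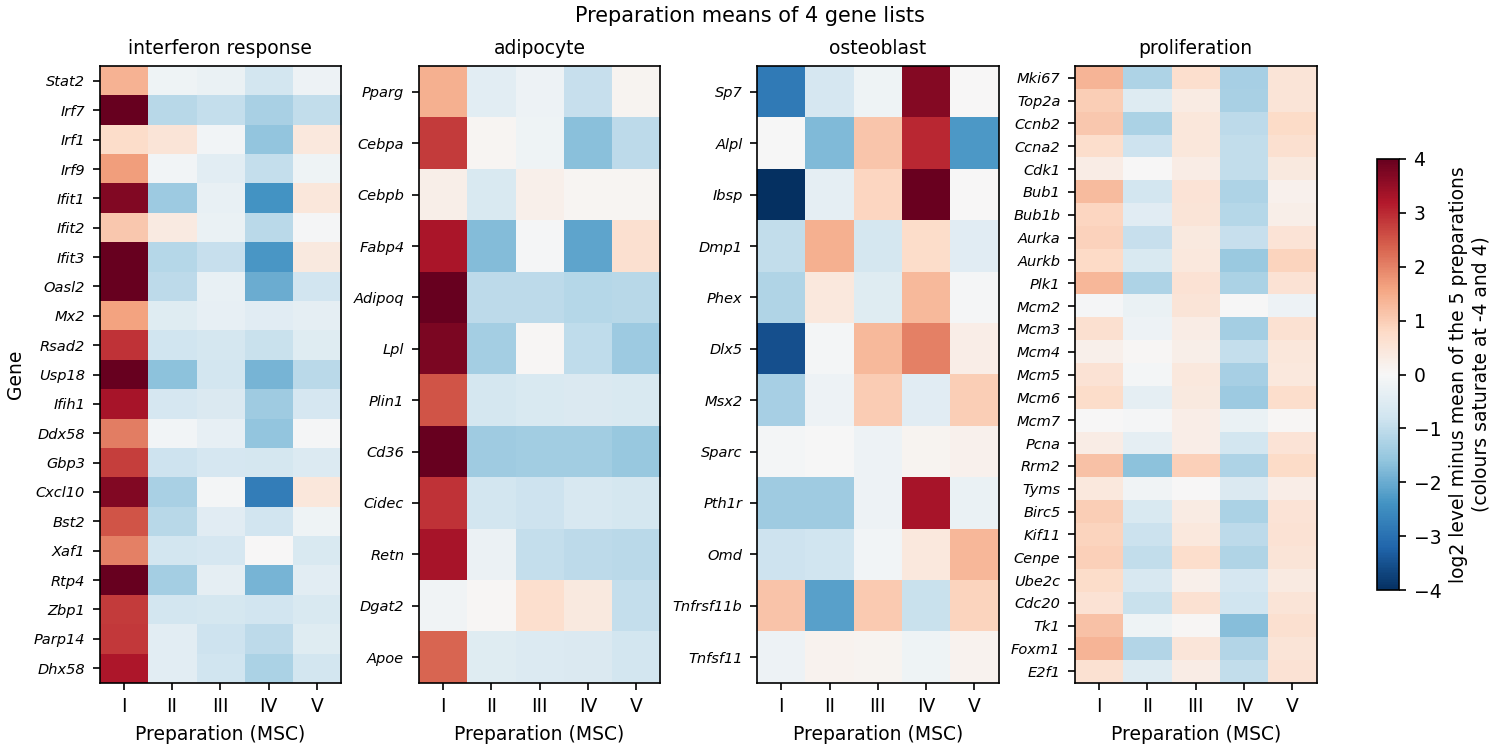
Mean log2 level of each tested gene (vertical axis) of the interferon response, adipocyte, osteoblast and proliferation lists in each preparation (horizontal axis), as the colour-coded difference from the mean of the 5 preparations, saturating at 4 log2 in either direction. Red is higher and blue is lower, with 20 of 21 interferon response genes called higher in MSC I (12 of 13 tested without MSC I replicate 1, 13 of 13 without replicate 2). In MSC IV 13 of 27 proliferation genes are called lower, and 2 without MSC IV replicate 2.

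MSC V combined high Grb10 with a shift within the Hox genes. The imprinted adaptor Grb10, which restrains insulin receptor signalling, was higher by 5.33 ± 0.29, adjusted p = 0.000127. Hoxa11 (3.32 ± 0.19) and Hoxa13 (3.06 ± 0.15), which pattern the distal limb, were higher, while Hoxc8 (-3.05 ± 0.24), Hoxc6 (-2.98 ± 0.27), Hoxc5 (-2.90 ± 0.17) and the hindlimb transcription factor Pitx1 (-2.71 ± 0.15) were lower. Of 27 Hox genes 3 were higher and 8 lower, also when adjusted over the list alone, and the list was not called (median -0.12, adjusted p = 0.319, and adjusted p = 0.831 with an estimated correlation). The higher genes fell to 1 of 26 tested without MSC V replicate 1. Other higher genes were Itgbl1 (4.28 ± 0.28), the cadherins Cdh18 (3.59 ± 0.18) and Cdh13 (3.45 ± 0.29), the melanocortin receptor Mc5r (3.20 ± 0.42) and the microfibril protein Mfap5 (2.95 ± 0.17). Lower genes were the zinc-finger gene Zfp991 (-4.29 ± 0.20, adjusted p = 9.99e-05), the small heat shock protein Hspb8 (-4.01 ± 0.15), the RNA-binding protein Rbpms (-3.47 ± 0.15) and the prostaglandin synthase Ptges (-2.83 ± 0.34). The opioid precursor Penk was higher by 4.53 ± 0.88, adjusted p = 0.0201, but lost its call without MSC V replicate 1 (4.95, adjusted p = 0.0972) or replicate 2 (4.10, adjusted p = 0.11).

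Of 25 structural matrix genes 2 were higher in MSC V, Postn (2.20) and Fbln2 (1.14), and the list was called (median 0.50, adjusted p = 1.98e-05, and adjusted p = 0.752 with an estimated correlation). There were 3 higher and 1 lower when adjusted over the list alone. Over all genes there were 4 higher without MSC II replicate 2, 1 without MSC V replicate 1 and 6 with MSC I left out of the reference. Fbln2 lost its call without MSC V replicate 1 (adjusted p = 0.0612), and Postn with MSC I left out of the reference (adjusted p = 0.101). Of 15 cholesterol synthesis genes 1 was higher, the sterol carrier Stard4 (median 0.56, adjusted p = 0.000205, and adjusted p = 0.773 with an estimated correlation). The count was 3 when adjusted over the list alone, and 2 over all genes without MSC III replicate 2 or with MSC I left out of the reference. Stard4 lost its call without MSC II replicate 1, MSC III replicate 1, MSC IV replicate 1 or 2, or MSC V replicate 1 or 2, with adjusted p from 0.0503 to 0.209. Of 12 contractile genes 1 was higher, calponin, Cnn1 (median 0.30, adjusted p = 0.00995, and adjusted p = 0.752 with an estimated correlation). The count was also 1 when adjusted over the list alone, 2 without MSC II replicate 2 or MSC V replicate 2 and 3 with MSC I left out of the reference. The list's call was lost without MSC V replicate 1 (adjusted p = 0.0723), while its median was 0.49 without MSC V replicate 2. Cnn1 lost its own call without MSC III replicate 1 (adjusted p = 0.0531) or MSC V replicate 1 (adjusted p = 0.194). The proliferation list was higher (median 0.65, adjusted p = 0.000592, and adjusted p = 0.831 with an estimated correlation) although limma called 0 of its 27 genes, and 0 when adjusted over the list alone. Its median was 0.0867 (adjusted p = 0.404) without MSC V replicate 1 and 1.19 (adjusted p = 8.08e-08) without MSC V replicate 2. The median was 1.00, with 1 gene called, when MSC I was left out of the reference (adjusted p = 1.24e-05, and adjusted p = 0.803 with an estimated correlation). The structural matrix, contractile and proliferation lists were lower in MSC IV (medians -1.06, -1.13 and -1.41). MSC IV was part of the reference and was not left out, so the higher lists of MSC V were not separated from its low levels. The adipocyte list (median -1.05, adjusted p = 0.000763, and adjusted p = 0.67 with an estimated correlation) and the interferon response list (median -0.55, adjusted p = 0.00038, and adjusted p = 0.397 with an estimated correlation) were lower. They had 4 of 12 and 2 of 21 genes called, the same numbers when adjusted over each list alone. The counts were 2 and 0 without replicate 1 or replicate 2 of MSC I, with 8 and 13 genes tested. The adipocyte count was 1 without MSC V replicate 1, and the interferon count 4 without MSC V replicate 2. With MSC I left out of the reference their medians were -0.0731 (adjusted p = 0.902) and 0.31 (adjusted p = 0.000108, and adjusted p = 0.752 with an estimated correlation), the second in the opposite direction with 3 genes called higher. The interferon call was also lost without MSC I replicate 1 (adjusted p = 0.486) or replicate 2 (adjusted p = 0.355), and its median was -0.35 without MSC V replicate 1. The adipocyte call was lost without MSC I replicate 1 (adjusted p = 0.0868). In all, 232 genes were called higher and 158 lower in MSC V, 390 together, and 187 together without MSC V replicate 1.

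The pairs that held MSC I or MSC IV differed in the most genes. MSC I and MSC IV differed in 2231 genes, MSC I and MSC II in 1633, MSC I and MSC III in 1239 and MSC I and MSC V in 1155. MSC IV differed from MSC V in 1195 genes, from MSC II in 994 and from MSC III in 877. MSC II and MSC V differed in 610 genes, MSC II and MSC III in 331, and MSC III and MSC V in 227. Single arrays moved several of these counts by more than 1.5 times. Without MSC I replicate 1 the count for MSC I and MSC III was 714. Without MSC II replicate 2 the counts were 593 for MSC II and MSC IV and 344 for MSC II and MSC V. Without MSC IV replicate 2 they were 562 for MSC II and MSC IV, 398 for MSC III and MSC IV and 625 for MSC IV and MSC V. MSC III and MSC IV had 412 without MSC III replicate 2, and MSC IV and MSC V had 747 without MSC V replicate 1. MSC II and MSC III had 180 without MSC II replicate 1, 157 without MSC II replicate 2, 151 without MSC III replicate 1 and 146 without MSC III replicate 2. MSC III and MSC V had 85 without MSC III replicate 1, 88 without MSC III replicate 2, 110 without MSC V replicate 1 and 100 without MSC V replicate 2.

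Genes of whole chromosomes were shifted together in some preparations, a comparison made because cultured mouse stromal cells of high passage can gain or lose chromosomes. In MSC II the 547 tested genes of chromosome 10 had a median difference of 0.54 log2, with 92.7% of them higher, and the 426 genes of chromosome 13 a median of -0.44. In MSC I chromosome 10 had a median of -0.43, chromosome 3 of -0.34 and chromosome 16 of -0.29, while chromosome 2 had 0.32 and chromosome 1 had 0.27. MSC II also had -0.28 for chromosome 1 and 0.26 for chromosome 11. MSC III had 0.29 for chromosome 12, MSC V had 0.26 for chromosome 13 and -0.25 for chromosome 12, and the X chromosome had -0.25 in MSC IV. In camera with the preset correlation of 0.01, 62 of 100 tests of a chromosome in a preparation were called, and 31 of these calls held with an estimated correlation, the 13 shifts given above among them. These were the shifts of at least 0.25 log2, a minimum chosen after seeing the data, that held with an estimated correlation. Chromosome 14 in MSC II was called with a median of 0.34 and 83.6% of its genes higher (adjusted p = 2.39e-11), but did not hold (adjusted p = 0.0775 with an estimated correlation). Without the low-value filter, which adds genes near the floor of the array, all 14 medians fell by over 1.5 times, to an absolute 0.0271 to 0.24, and all 14 stayed called. Because each preparation was set against the other four, a shift in one preparation lowers or raises the others by a smaller amount. Of the 13 shifts, 4 were not particular to 1 preparation, with a median difference near 0 from another. MSC III was 0.0117 from MSC IV for chromosome 12, MSC V was 0.013 from MSC I for chromosome 13 and -0.0586 from MSC I for chromosome 12, and MSC I was 0.0177 from MSC V for chromosome 1.

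**Figure D5:**
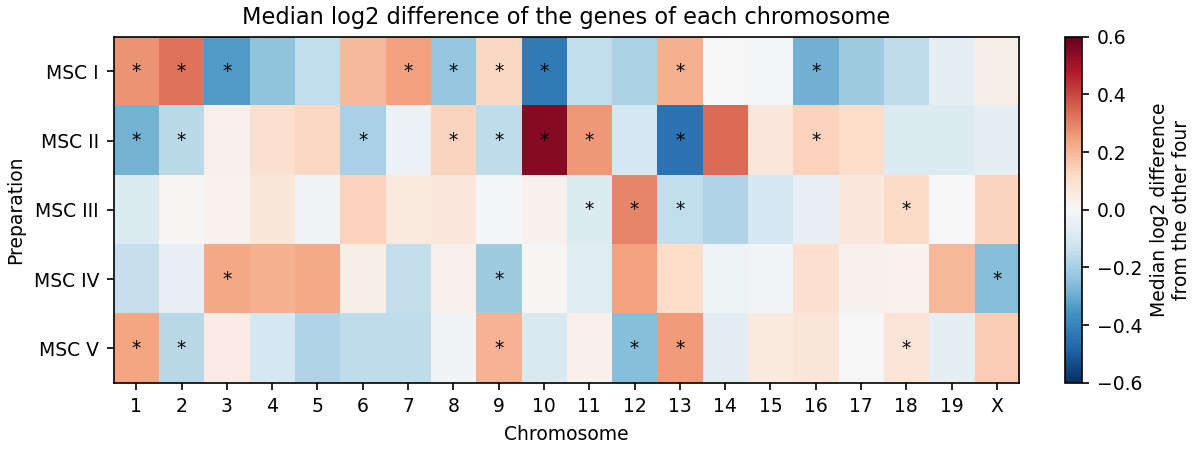
Median log2 difference of the tested genes of each chromosome (horizontal axis) in each preparation (vertical axis) from the other four, with red higher and blue lower; asterisks mark the 31 calls that hold with an estimated correlation. The strongest is chromosome 10 in MSC II, at 0.54.

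Markers of other cell types were mostly below the low-value filter. Of the macrophage genes 3 of 17 were tested, and Cd68 was higher in MSC V (1.60 ± 0.13) and Cd74, an antigen presentation chaperone, lower in MSC I (-1.59 ± 0.44). Of 12 genes of other blood cells 2 were tested, the stem cell factor receptor Kit, higher in MSC I (4.91 ± 0.29), and Cd34, lower there (-4.21 ± 0.47). Cd34 was also called higher in MSC III and MSC V. Those calls were lost with MSC I left out of the reference (1.49, adjusted p = 0.128, and 1.52, adjusted p = 0.0707). The MSC III call was lost as well without either array of MSC II or without replicate 2 of MSC I, MSC III, MSC IV or MSC V. The MSC V call was lost without either array of MSC V. Of 11 epithelial genes 1 was tested, the keratin Krt19, which was higher in MSC I (2.61 ± 0.52) and lower in MSC IV (-2.70 ± 0.52). Krt19 was also called lower in MSC II. That call was lost with MSC I left out of the reference (-1.29, adjusted p = 0.151) and without either array of MSC II or of MSC IV. It was also lost without MSC I replicate 2 or MSC III replicate 2. Of 14 endothelial genes 1 was tested and not called, and of 10 glial and neural crest genes 2 were tested, of which Ncam1 was lower in MSC I (-1.16 ± 0.27). Without 1 array, calls were lost for Cd74 (MSC I replicate 1, adjusted p = 0.205), Ncam1 (MSC I replicate 1, adjusted p = 0.0907) and Krt19 (MSC I replicate 2, adjusted p = 0.061, and in MSC IV without its replicate 2, adjusted p = 0.0696). With the check of X and Y genes, these were the 6 lists with fewer than 4 tested members, which camera did not test. None of the 5 tested muscle genes differed among the preparations in the F test (lowest list adjusted p = 0.539), although 1 did without MSC II replicate 1, and none of the 10 housekeeping genes did (lowest list adjusted p = 0.545). The noncoding RNA Xist, which silences an X chromosome in females, was the tested gene of the X and Y check and was lower in MSC IV (-2.21 ± 0.14) and MSC V (-1.35 ± 0.14). Its means were 12.35 in MSC I, 12.29 in MSC II, 12.52 in MSC III, 9.67 in MSC IV and 10.35 in MSC V.

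Several lists held genes that differed among the preparations without a call in any preparation. Over all tested genes 29.1% differed, and the share in the unfolded protein and amino acid response list lay below that. Of 16 stromal surface markers 11 differed (lowest list adjusted p = 0.187), and 7 of 15 tested without MSC IV replicate 2. Endoglin, Eng, and the ectonucleotidase Nt5e were higher in MSC IV (3.91 ± 0.0912 and 4.26 ± 0.30). All 7 tested chondrocyte genes differed (lowest list adjusted p = 0.215), with the cartilage transcription factor Sox9 higher in MSC V (2.00 ± 0.22). Of 16 matrix proteases and inhibitors 10 differed (lowest list adjusted p = 0.0835), and the collagenase Mmp13 was lower in MSC II (-3.74 ± 0.48). Of 12 immunomodulation genes 8 differed (lowest list adjusted p = 0.236), with the ectonucleotidase Entpd1 higher in MSC II (2.77 ± 0.18). Differences were found in 9 of 16 genes of the TGF-beta and BMP response (lowest list adjusted p = 0.195) and 7 of 18 antioxidant and xenobiotic genes (lowest list adjusted p = 0.458). They were also found in 6 of 14 p53 targets (lowest list adjusted p = 0.14), 5 of 10 cell cycle inhibitors and telomerase genes (lowest list adjusted p = 0.262) and 1 of 16 genes of the unfolded protein and amino acid response (lowest list adjusted p = 0.199). When adjusted over each list alone, these counts were 11 for the surface markers, 7, 10, 8, 10, 7, 7 and 5 for the next lists in that order, and 0 for the last, against 1 over all genes by limma's F test. That last count ranged from 0 (without MSC I replicate 1 or MSC IV replicate 2) to 5 (without MSC V replicate 2). Over all 26 tested lists, 34 of 130 tests were called by camera with the preset correlation. With an estimated correlation 0 held, where the lowest adjusted p was 0.0754 and 10 tests had an unadjusted p under 0.05. The directional test of limma's fry called 35. Camera asks whether a list changed more than the other genes, while fry asks only whether the list changed. The calls of fry are therefore no check on those of camera. Fry did not call the proliferation list in any preparation (adjusted p = 0.182, 0.286, 0.383, 0.0681 and 0.306 in MSC I to MSC V). Nor did it call the structural matrix list in MSC III (adjusted p = 0.171) and MSC V (adjusted p = 0.0681), the glycolysis and hypoxia list in MSC III (adjusted p = 0.0864) or the cholesterol synthesis list in MSC V (adjusted p = 0.171).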

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

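Leaving MSC I out of the reference was chosen after the results were seen, and the other alternatives before. No direction was reversed by leaving out an array, a filter, a normalisation, the variance model or the block. With each preparation averaged to 1 value and set against the spread of the other four, limma called 212 genes in MSC I, 2 in MSC II, 0 in MSC III, 42 in MSC IV and 0 in MSC V, with 901, 167, 60, 671 and 135 genes at an unadjusted p under 0.05. That test has fewer values and takes its error from the spread among preparations, and the 2 were not separated. With an estimated correlation 31 chromosome shifts and 0 gene lists were called. The stricter filter, with fewer genes tested, gave 1862 genes differing among the preparations, 854, 328, 130, 771 and 223 in MSC I to MSC V, and for pairs 992 (I and II), 717 (I and III), 1363 (I and IV), 642 (I and V), 158 (II and III), 592 (II and IV), 345 (II and V), 530 (III and IV), 105 (III and V) and 711 (IV and V). With only the 4 arrays of a pair, MSC II and MSC V differed in 304 genes and MSC III and MSC V in 132, with fewer samples in the fit. After centring the arrays the median of all genes lay within 0.072 log2 of 0 in each preparation.

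The replicate numbers were checked for pairing. The deviations of same-numbered arrays correlated at -0.555 to 0.203 over 10 pairs of preparations, 1 of them over 0.1, and 0 arrays correlated best with an array of their own number, so the numbers were not taken to pair the arrays. With the replicate block the count for MSC II and MSC III was 217 and for MSC III and MSC V 135, and it moved no other count by over 1.5 times.

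Leaving out each array in turn gave 2590 to 3300 genes differing among the preparations, 1034 to 1493 in MSC I, 295 to 560 in MSC II, 76 to 238 in MSC III, 703 to 1314 in MSC IV and 187 to 383 in MSC V. For pairs it gave 1265 to 1660 (I and II), 714 to 1264 (I and III), 1744 to 2252 (I and IV), 846 to 1158 (I and V), 146 to 335 (II and III), 562 to 1091 (II and IV), 344 to 590 (II and V), 398 to 906 (III and IV), 85 to 223 (III and V) and 625 to 1232 (IV and V). It gave 59 to 66 chromosome calls and 29 to 40 list calls. Of 559 calls of named or listed genes, 232 were lost and 79 were not tested, under the low-value filter, without at least 1 array, and of 34 list calls 14 were. The cause was not tested.

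With MSC I left out of the reference, 362 of 564 genes called in MSC II, 131 of 249 in MSC III, 866 of 1206 in MSC IV and 269 of 390 in MSC V were called again. Camera then also called the osteoblast list lower in MSC II (median -1.32, adjusted p = 0.0101). In MSC III it called niche factors (1.13, adjusted p = 0.00137), contractile (0.35, adjusted p = 0.00457) and inflammatory genes (1.01, adjusted p = 0.00742) higher. In MSC V it called niche factors (0.449, adjusted p = 0.0369) and class I genes (0.194, adjusted p = 0.0189) higher. These added calls did not hold with an estimated correlation (adjusted p from 0.752 to 0.803). MSC IV stayed in the reference of MSC II, III and V. Its own medians with MSC I left out were -2.03 for niche factors, -1.06 for contractile, -0.686 for inflammatory and -0.595 for class I genes. Its osteoblast median was 0.983, and that list was not called there. MSC IV was not left out of any reference, so these added calls were not separated from its levels. The direction reversed in MSC II for Cd36 (0.00194), Adipoq (0.0563) and the class I list (0.11), in MSC III for Cd36 (0.0562), Adipoq (0.0358), H2-Q4 (0.34), Ifit3 (0.0803), Irf7 (0.18) and the adipocyte (0.14), class I (0.0453) and interferon response lists (0.0936), in MSC IV for Cd36 (0.0512) and Postn (-0.36), and in MSC V for H2-Q4 (0.0512), Irf7 (0.13), Usp18 (0.32) and the interferon response list (0.31). Leaving MSC I out removes its extreme levels of these genes from the reference.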

Other observations

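The tests of male cells, of renewed X expression, of blood cells and of a shift of all genes were chosen after the result was seen, as were the 0.25 log2 minimum for the chromosome shifts and the demand that a value pass its bound by more than its spread.

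The preparations differed in which Wnt genes they expressed, a pathway that guides the choice between bone and fat. Of 19 tested genes 17 differed among the preparations, also when adjusted over the list alone, and the list was not called in any preparation (lowest adjusted p = 0.214). MSC IV had 6 higher and 8 lower members (3 of 17 tested higher without MSC IV replicate 1 and 2 of 17 without replicate 2), with the ligands Wnt5a (2.19 ± 0.22) and Wnt4 (1.27 ± 0.24) and the inhibitor Dkk1 (5.22 ± 0.51) higher, and the antagonist Sfrp1 (-4.60 ± 0.31) and the transcription factor Lef1 (-1.70 ± 0.22) lower. In MSC I Lef1 (2.56 ± 0.22) was higher and Wnt5a (-1.76 ± 0.22) lower, where MSC I and MSC IV are each part of the other's reference. Growth factors differed as well: Pdgfa, a mitogen of stromal cells, was higher in MSC IV (2.23 ± 0.13), and the insulin-like growth factor Igf2 was higher in MSC I (4.47 ± 0.32) and lower in MSC V (-2.90 ± 0.32).

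Imprinted genes, which are expressed from the copy of one parent, took different combinations. Grb10 was higher in MSC V (5.33 ± 0.29), while Slc38a4, an amino acid transporter, was higher in MSC I (4.67 ± 0.18). Igf2r, the receptor that clears Igf2, was lower in MSC V (-1.28 ± 0.10). In MSC IV 6 of 13 tested imprinted genes were lower (3 without MSC IV replicate 2) and 2 higher (1 without MSC IV replicate 1), also when adjusted over the list alone, and the list was not called there (median -0.76, adjusted p = 0.147, and adjusted p = 0.773 with an estimated correlation).

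The 13 chromosome-wide shifts of at least 0.25 log2 that held with an estimated correlation could come from a change in chromosome number in part or all of the cells. In 13 of 13 each of 3 equal stretches of the chromosome, in the order of its genes, had a median at or above 0.5 of the whole, which such a change would give. Any shift spread along the chromosome would give it too, and the shifts were chosen by their whole median. The stretches therefore show only that the shifts were not confined to 1 part. Their medians were even for chromosome 10 in MSC II (0.529 to 0.569) and uneven for X in MSC IV (-0.179 to -0.405). Against a trend with expression level left by the normalisation, a loess fit on mean expression left a mean share of 1 of the shift (0.942 to 1.07). The share of genes on the side of the shift lay on average 31.7 percentage points above that of other genes, but the shifts were chosen by their median, so this decides nothing about a few strongly changed genes. A whole extra copy in all cells against a reference with none would give 0.585 log2. Of the 13 shifts, 4 lay within 0.1 log2 of another preparation, so a change there would be shared by more than 1 preparation or lie in the others. For chromosome 10 the differences of MSC II from single preparations ran from 0.386 to 0.777, the largest from MSC I, where this chromosome was lower, so the number of copies was not inferred. Regulation of a whole chromosome was not separated from copy number, and a chromosome count of these cells would be needed.

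The level of Xist minus that of MSC I, II and III was -2.72 log2 in MSC IV and -2.03 in MSC V. Renewed expression of the silent X is argued against in MSC IV, where X genes lay at -0.245 (SE 0.0327) against autosomal genes. Against the other four, the 2 arrays of MSC IV had X medians of -0.20 and -0.29. In MSC V the X genes lay at 0.0996 (SE 0.0188) against autosomal genes, too near the bound of 0.1 to exclude renewed expression. The SE in these tests came from resampling the X genes or from the SD of the 4 escape genes. They do not measure the spread between arrays. Cells of male origin, against the labels, would raise the Y-linked genes Eif2s3y, Kdm5d and Uty and would lack Xist. The Y-linked genes lay at most 0.0374 log2 above MSC I, II and III, which met the bound against male cells. Their levels were 4.73 to 5.11 in all preparations, near the floor of the array. Xist, although lower, stayed above the low-value level in MSC IV and MSC V. These values argue against male cells as the whole of MSC IV or MSC V. A part of male cells stays open, because no male sample showed that the Y-linked probe sets respond. Loss of the inactive X, tested as the median of 4 escape genes minus that of all X genes, stays open, with -0.014 (SE 0.1) in MSC IV and -0.212 (SE 0.0845) in MSC V. Under the bounds alone, without the demand on the spread, MSC V would have met the bound for loss (-0.2), and MSC IV would have met the bound against it (-0.05).

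The higher interferon response genes of MSC I may reflect a biological state of that preparation, which was not tested apart from its other properties. The housekeeping median of -0.00399 met the bound against a shift of all genes. RMA normalises arrays to a common distribution, which would remove such a shift. The median therefore shows only that none remained in the normalised values. Macrophages or other blood cells stay open. Their 29 genes had a median difference of -0.0177 log2, with Kit (4.91) the 1 gene over 1 log2, but 24 of them did not pass the low-value filter. The 5 that passed went both ways, with Cd68 (-0.336), Cd14 (-0.654), Cd74 (-1.59) and Cd34 (-4.21) below the other four and Kit above. Interferon transcripts of the same cells stay open too. Ifna genes had a median difference of 0.0357 and Ifnb1 one of -0.10, but the median Ifna level and the Ifnb1 level in MSC I (5.34 and 5.05) lay near the floor of the array. Of 10 Ifna genes, 1 lay above the low-value filter, Ifna5, at 7.87 in MSC I with a difference of 0.0125. The bounds alone would have excluded both sources, and the levels of most genes were judged too low for that after they were seen.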
